A study of Homo sapiens with 9 samples.

How the data were processed

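RNA was measured by bulk RNA-seq in 9 libraries of human primary mesenchymal stem cells on day 7 of osteogenic induction, 3 libraries for each of 3 hairpins (shControl, shCTR9#3 and shCTR9#5). Libraries were made from 100 ng of total RNA with a SMARTer mRNA-Seq kit and read as single ends of 50 bp, per the labels' protocols. CASAVA 1.8, STAR 2.7.9a, Subread 2.0.1 and DESeq2 1.36.0 with hg38 were named, per the submitters' processing notes. The deposited values are raw counts of reads per gene, made with featureCounts 2.0.1 over the exons of the hg38 NCBI RefSeq annotation, per the file headers. Every alignment of a read that mapped to many places was counted, a read was counted for each gene it overlapped, and strand was not used, per the file headers. Input reads had been trimmed, per the file headers, and the trimming tool is not given in the sources used here. Which values the submitters computed with DESeq2 is not given in the sources used here.

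Each file held 54628 genes, of which 52040 matched the RefSeq gene table and 19519 were protein-coding. Ribosomal RNA names took 36 of them and 37 lay on chromosome M. Groups were taken from the labels, and no library was left out. Total counts ranged from 64703760 to 73417825 in shControl and from 6469479 to 15794736 in the knockdown libraries. Genes on chromosome Y and XIST are not reported here.

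Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3. Genes were kept by filterByExpr over the 3 groups, which left 16355 genes, 12100 of them protein-coding. Libraries were scaled by TMM, with factors from 0.980 to 1.18 and 0.519 in shCTR9#5 replicate 2. A quasi-likelihood model with a coefficient per group was fitted to all 9 libraries, and genes were called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold change. The common biological coefficient of variation was 7.39%. Contrasts were each CTR9 hairpin against shControl, the mean of the CTR9 hairpins against shControl, and shCTR9#5 against shCTR9#3. A gene counted for both hairpins when it was called with each in the same direction. Levels are CPM, computed with the TMM-scaled library size. For a group with 0 counts a fold was computed against a floor of 3 counts over the group, and ratios printed for groups of 1 to 3 counts have an exact 95% interval. For other groups that low only the counts are printed.

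Gene lists were tested with camera on the edgeR object with a preset correlation of 0.01 and again with an estimated correlation, where at least 5 members were tested, and adjusted p-values cover 87 tests. The 32 lists were the PAF1 complex, elongation and H2B ubiquitylation factors, H3K27, H3K4 and H3K79 methylation enzymes, osteoblast genes, the BMP, TGF-beta and Wnt pathways, Hedgehog, Notch and FGF genes, fibrillar collagens and bone matrix, matrix proteases, adipocyte and cartilage genes, glucocorticoid-induced genes, cell division genes, p53 targets and senescence genes, interferon response, inflammatory cytokines and NF-kB targets, endoplasmic reticulum and amino acid stress, heat shock, hypoxia and glycolysis, cholesterol synthesis, mitochondrial mRNAs, nuclear oxidative phosphorylation, ribosomal proteins, histones, HOX genes, immediate early genes, mesenchymal stem cell surface markers, smooth muscle and pericyte markers, and endothelial, blood cell and epithelial markers. The lists, tests, contrasts, most alternatives and the rule for naming genes were chosen before the data were examined. That rule named the PAF1 complex and 8 osteoblast genes, the 12 higher and 12 lower genes of a mean CPM of at least 5 with the largest smaller change of both hairpins and no overlap between knockdown and control libraries, the 5 higher and 5 lower genes between the hairpins by the same CPM minimum, and up to 4 members of each list with the largest mean change. Some genes that this rule named are not reported here. Genes named for other reasons are the 8 called in opposite directions, chosen after their values were seen.

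The fit was tested on simulated data of 16355 genes drawn from the means, spread and depth of these libraries, with 50 genes changed at each of the folds 1.25, 1.5, 2 and 4. For shCTR9#3 against shControl 24%, 48%, 78% and 96% of the changed genes were recovered at these folds, and for shCTR9#5 against shControl 8%, 42%, 74% and 94%. In a separate simulation with the change in both CTR9 hairpin groups, 8%, 42%, 76% and 92% were recovered with both and 22%, 62%, 94% and 98% for their mean. In a further one, for shCTR9#5 against shCTR9#3, 4%, 36%, 68% and 96% were recovered. Unchanged genes called numbered 15, 3, 3, 9 and 3 in these comparisons. Of 10 simulated lists of 25 genes, the 3 shifted by a fold of 1.5 passed and 0 of the others.

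Alternatives were relative log expression scaling, library totals alone, DESeq2, limma-voom, no filter, a filter of 1 CPM, a replicate block, 6 libraries per fit, a threshold of 0.01, a log2 fold minimum of 1, leaving out each library in turn, and for lists an estimated correlation and a mean CPM of at least 5. Fits on protein-coding genes only, on libraries thinned to 1345401 protein-coding counts, and without structured RNA classes were chosen after seeing the data.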

Results

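Gene expression was measured by bulk RNA-seq in human primary mesenchymal stem cells, stromal cells that can form bone, cartilage and fat, on day 7 of culture in osteogenic medium, which holds β-glycerophosphate, an ascorbate derivative and the glucocorticoid dexamethasone. The cells carried a control short hairpin RNA (shControl) or 1 of 2 hairpins against CTR9 (shCTR9#3 and shCTR9#5), with 3 libraries in each of the 3 groups. CTR9 is a subunit of the PAF1 complex, which binds elongating RNA polymerase II and is needed for histone modification over transcribed genes. The series asked which genes depend on CTR9 when hMSCs begin to turn into osteoblasts. Counts summed to 64703760, 69197596 and 73417825 in the shControl libraries, to 12017633, 10206367 and 9001611 in shCTR9#3 and to 7356704, 15794736 and 6469479 in shCTR9#5. Protein-coding genes held 23046192 to 23554702 counts per library in shControl, 1984038 to 2284491 in shCTR9#3 and 1345401 to 1500558 in shCTR9#5. Ribosomal RNA took 54.4% ± 1.66, 66.3% ± 2.41 and 71.5% ± 8.90 (SD, n = 3) of the counts in the 3 groups, with 81.5% in replicate 2 of shCTR9#5. Every knockdown library was shallower than every control library, and the labels name no library batch. The labels do not say whether replicates were separate cultures or donors, and p-values measure only the spread between these libraries. Every pair of libraries of the same group differed beyond sampling noise, with chi-square per degree of freedom of 1.363 to 4.47.

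CTR9 was far lower with both hairpins. The gene (chromosome 11, 10751246 to 10779746 of hg38, plus strand) stood at 31.3 ± 0.896 CPM in shControl, 3.61 ± 0.629 in shCTR9#3 and 3.82 ± 0.240 in shCTR9#5 (SD, n = 3). Its counts per group were 6758, 124 and 89. It fell 8.71-fold with shCTR9#3 and 8.20-fold with shCTR9#5 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.78e-14 and 1.58e-13). All 6 knockdown libraries lay below all 3 control libraries. Of the other members of the PAF1 complex, RTF1, which helps to promote histone H2B ubiquitylation, rose by a log2 fold change of 0.30 and 0.20, with 16.996 ± 0.583 CPM in shControl against 20.9 ± 0.768 and 19.6 ± 1.18. PAF1, LEO1, CDC73 and WDR61 (SKIC8) were not called with both hairpins, with log2 fold changes of -0.09, -0.19, -0.26 and -0.09 in shCTR9#3 and -0.31, -0.30, -0.26 and -0.51 in shCTR9#5. In the mean of the hairpins PAF1, LEO1 and CDC73 were called lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0429, 0.00845 and 0.0139). These calls were lost in 11, 2 and 3 of the alternatives, and CDC73 also turned direction after thinning. Adjusted over the list alone, 1 of the 6 members was higher and 2 were lower with both. CTR9, the target of the hairpins, is among the lower members and counts in every test of this list. The list as a whole did not pass (camera, adjusted p = 0.238 for the mean of the hairpins, 0.319 with an estimated correlation, 0.00194 to 0.555 over the alternatives), but it passed downward when no filter on low counts was used, with 4 of 6 lower. Counting without strand, exons of PAF1 overlap those of SAMD4B by 78 bases. RTF1 lost its call when the libraries were scaled by their totals alone (adjusted p = 0.633, from 2.31e-05 to 0.766 over the alternatives) and stood at a log2 fold change of -0.04 when no filter on low counts was used.

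**Figure D1:**
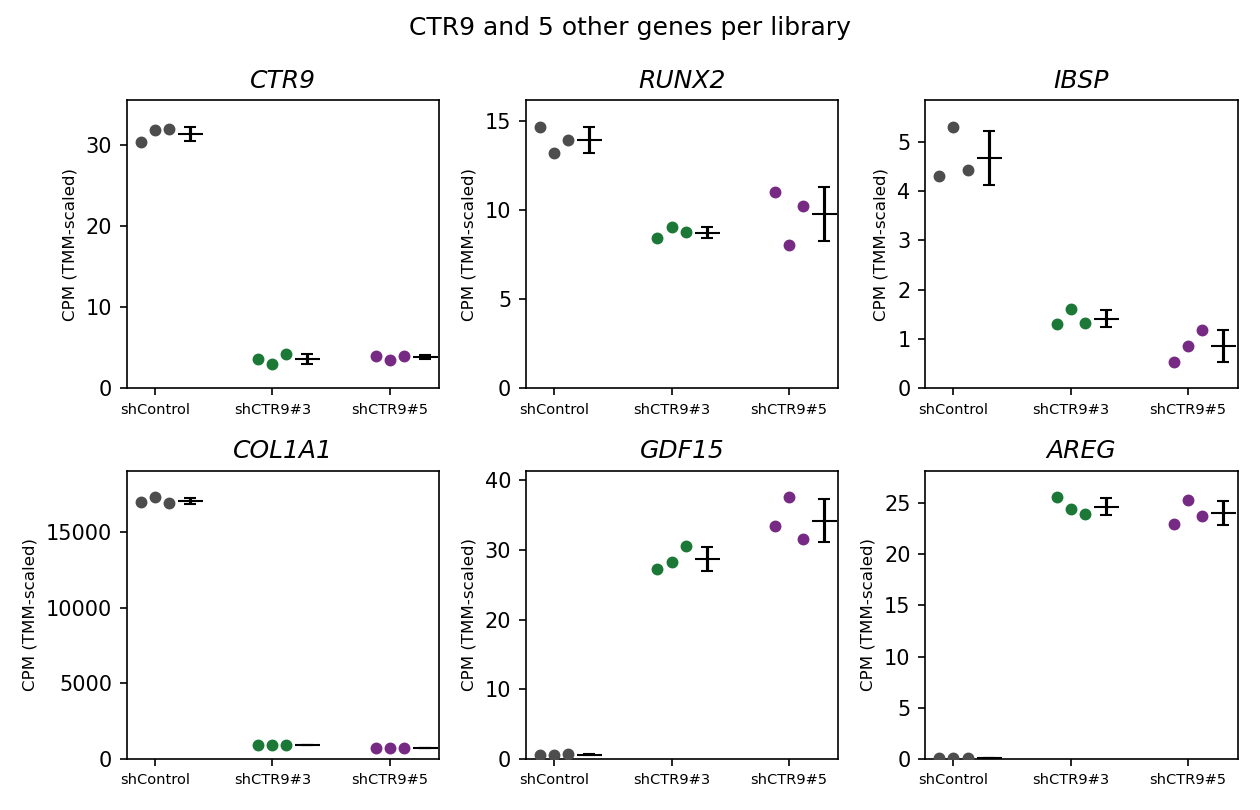
TMM-normalised level (CPM) of CTR9, RUNX2, IBSP, COL1A1, GDF15 and AREG in each of the 9 libraries, with the mean and SD of each group (n = 3), each panel on a linear axis from 0. CTR9, RUNX2, IBSP and COL1A1 lie lower in the 6 knockdown libraries than in the 3 control libraries, and GDF15 and AREG lie higher.

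With shCTR9#3, the lists of fibrillar collagens and bone matrix, smooth muscle and pericyte markers and cell division genes were lower (camera, adjusted p = 2.98e-27, 2.1e-30 and 8.66e-05, and 0.00179, 0.00138 and 0.0323 with an estimated correlation). COL1A1, the main chain of bone collagen (chromosome 17, 50184096 to 50201649), fell from 17077 ± 215 to 916 ± 21.8 CPM (SD, n = 3). TAGLN, an actin-binding protein of smooth muscle, fell from 475 ± 18.9 to 11.2 ± 1.14 CPM, and MKI67, a marker of dividing cells, from 24.97 ± 0.563 to 0.911 ± 0.408 CPM. VEGFA, the angiogenic growth factor, rose from 17.3 ± 0.211 to 96.3 ± 3.01 CPM, and ADAMTS5, a protease that cleaves aggrecan, rose from 2.87 ± 0.297 to 113 ± 0.296 CPM. The edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05 called 5291 of 16355 genes higher and 5314 lower than in shControl. Of these, 2161 higher and 2307 lower genes changed by a log2 fold of at least 1. After all libraries were thinned to 1345401 protein-coding counts, 3276 and 3409 genes were called, and with library totals alone as the scaling, which moved the median log2 fold change of all genes to 0.11, 3215 and 2533. Without a filter on low counts 8089 genes were called lower.

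With shCTR9#5, the lists of fibrillar collagens and bone matrix and of smooth muscle and pericyte markers were lower (camera, adjusted p = 1.03e-37 and 1.19e-30, both 0.00179 with an estimated correlation). The cell division list was lower too (camera, adjusted p = 0.00172), with adjusted p = 0.0545 with an estimated correlation. COMP, a cartilage matrix protein, fell from 2037 ± 14.6 to 124 ± 4.78 CPM (SD, n = 3), and LEPR, the leptin receptor of marrow stromal cells (chromosome 1, 65420652 to 65641559), from 349.8 ± 13.8 to 15.1 ± 1.01 CPM. ACTA2, smooth muscle actin, fell from 433 ± 8.44 to 14.8 ± 2.81 CPM, and TOP2A, a topoisomerase of dividing cells, from 16.7 ± 0.370 to 0.689 ± 0.214 CPM. SLC3A2, a shared chain of amino acid transporters, rose from 9.49 ± 0.661 to 151 ± 2.99 CPM, and GDF15, a stress-induced cytokine, from 0.584 ± 0.0749 to 34.2 ± 3.05 CPM. The edgeR quasi-likelihood test called 5089 genes higher and 5131 lower at a Benjamini-Hochberg adjusted p under 0.05, and 2270 and 2527 of them changed by a log2 fold of at least 1. The mean ribosomal RNA share was highest in this group, through replicate 2 at 81.5%. Replicates 1 and 3 had 68.5% and 64.4%, within or near the 64.2% to 68.9% of shCTR9#3. With library totals alone as the scaling, which moved the median log2 fold change of all genes to -0.25, 1903 genes were higher and 4090 lower, so that higher genes made up 31.8% of the calls against 49.8% with TMM, and without a filter on low counts 7792 were lower.

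Across both hairpins, the genes with the largest rises included AREG, a ligand of the EGF receptor, GDF15, ADAMTS5 and NR4A2, an immediate early nuclear receptor. AREG (chromosome 4, 74445136 to 74455005) went from 0.0881 ± 0.00883 CPM in shControl to 24.7 ± 0.844 and 24.0 ± 1.19 (SD, n = 3), log2 fold changes of 8.06 and 8.03. GDF15 (chromosome 19, 18382170 to 18389176) rose by 5.61 and 5.86, ADAMTS5 (chromosome 21, 26917922 to 26967758) by 5.30 and 5.19, and NR4A2 (chromosome 2, 156324432 to 156332724) by 4.40 and 4.74. Others of the 12 genes of a mean CPM of at least 5 that rose most were the pseudogenes PDZPH1P and BNIP3P31 and 5 nuclear transfer RNA genes, TRM-CAT1-1, TRK-CTT4-1, TRK-TTT3-3, TRK-CTT2-1 and TRK-CTT2-4. BNIP3P31 had 0 counts in shControl and 342 and 394 with the hairpins, at least 712-fold and 1215-fold higher against a floor of 3 counts over the group. These genes are uncertain, because every alignment of a read that maps to many places was counted, and the olfactory receptor gene OR1F1, also among the 12, shares 73 exon bases with TRK-CTT4-1. Within each CTR9 hairpin the levels of all of them also ran in the order of the ribosomal RNA share of the libraries. BNIP3P31 was at 17.3, 25.9 and 6.82 CPM in shCTR9#5 replicates 1, 2 and 3, where ribosomal RNA took 68.5%, 81.5% and 64.4% of the counts. A technical part of these rises therefore stays open.

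The 12 genes of a mean CPM of at least 5 that fell most with both hairpins were expressed at 16.3 to 176 CPM in shControl and were near 0 after knockdown. PRELP, a leucine-rich proteoglycan of connective tissue (chromosome 1, 203475806 to 203491352), fell from 176 ± 3.55 to 1.01 ± 0.0861 and 1.23 ± 0.333 CPM, and its relative FMOD from 37.9 ± 1.47 to 0.600 ± 0.201 and 0.389 ± 0.232 CPM (SD, n = 3). CADM3, a cell adhesion molecule, fell from 118 ± 2.25 to 1.29 ± 0.429 and 0.467 ± 0.180 CPM, and CADM3-AS1, which lies on the other strand and shares 1318 exon bases with it, cannot be counted apart from it without strand. LEP, the hormone leptin, had 4901 counts in shControl and 3 with each hairpin, a ratio of 262 (95% counting interval 89.4 to 1269) for shCTR9#3 and 177 (60.4 to 857) for shCTR9#5. KIAA0040 had 3513, 3 and 1 counts, ratios of 187 (64.1 to 909.6) and 380 (68.1 to 15002). The remaining genes of the 12 were GGT5, CD24, IRAG1, SUSD2, EPHB6 and STEAP4, with log2 fold changes between -6.96 and -5.62. Intervals and floors cover counting error only.

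Both hairpins moved 4382 genes up and 4625 down by the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05 for each, 84.9% of the genes called with shCTR9#3 and 88.1% of those called with shCTR9#5. Independent lists of these sizes would share 1646 and 1667 genes, and 20 simulations of unchanged groups against the same controls shared 0. Across genes, which are not independent replicates, the log2 fold changes of the hairpins had a Pearson r of 0.956 and a Spearman rho of 0.939 (mean r 0.0774, from 0.0336 to 0.125, in the simulations), and 89.4% had the same sign (50.2%). Their covariance was 1.78 against 0.00658 in the simulations. The controls are too few to be split, so part of the excess may come from the shared controls. Only 8 genes were called in opposite directions, among them C3, COL6A3, FAP and PPIB, which are named because of these values. With libraries thinned to equal protein-coding counts 2834 genes were higher with both, with library totals alone 1835 higher and 2469 lower, and with no filter 6945 lower. TMM scaling centres the log2 fold changes (medians 0.0171 with shCTR9#3 and 0.0199 with shCTR9#5), so higher and lower are relative to the other genes. A fall shared by most genes would not be seen. Protein-coding genes held on average 33.7%, 20.9% and 16.3% of the counts in shControl, shCTR9#3 and shCTR9#5.

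**Figure D2:**
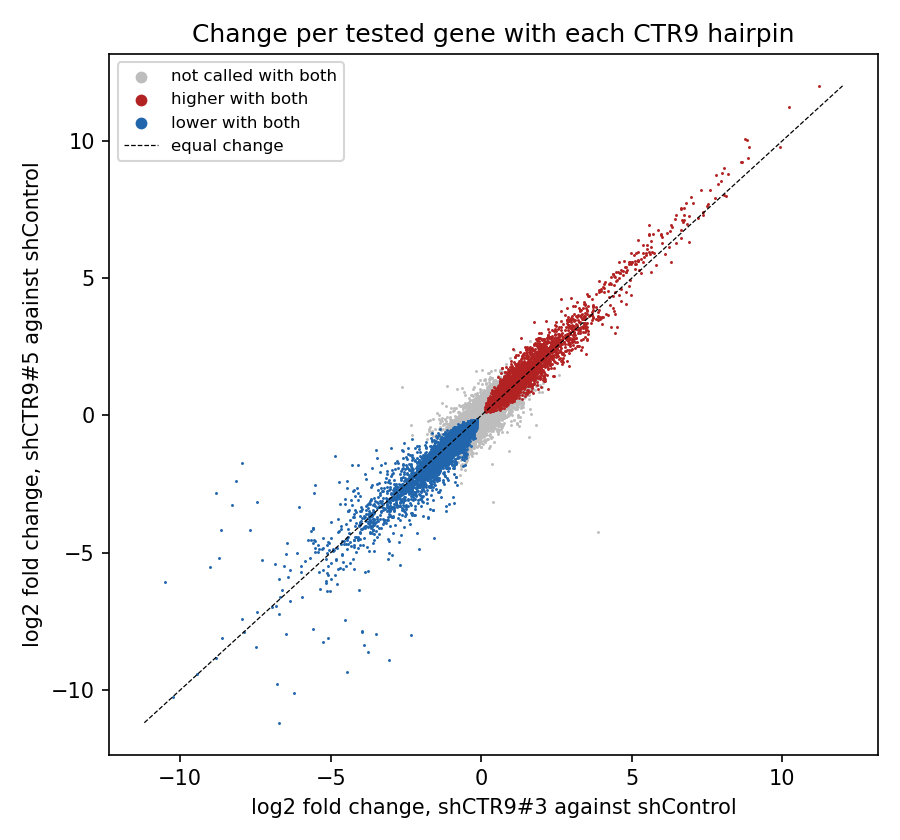
Log2 fold change against shControl of each tested gene with shCTR9#3 (horizontal axis) and with shCTR9#5 (vertical axis), where the dashed line marks equal change. Points lie along that line with a Pearson r of 0.956 across genes, and fitted values of genes with 0 counts in a group depend on the prior count.

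Both hairpins together, as their mean against shControl, addressed which pathways and cell identities moved with CTR9. Osteoblast genes, matrix genes, stromal surface markers, contractile genes, cartilage genes, cell division genes and genes of the TGF-beta and Wnt pathways fell, and p53 targets, amino acid stress genes, NF-kB targets and histone methylation enzymes rose. The mean contrast called 5788 genes higher and 5761 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of 29 gene lists with at least 5 tested members, camera put 10 lower and 5 higher than the other genes at an adjusted p under 0.05 over 87 tests, and 12 of the 15 held with an estimated correlation. Exceptions were cholesterol synthesis, mitochondrial mRNAs and immediate early genes. With camera on genes of a mean CPM of at least 5, the TGF-beta, cell division and inflammatory lists did not pass (adjusted p = 0.379, 0.163 and 0.119), nor did the immediate early list, and with limma-voom neither did the TGF-beta and cartilage lists (adjusted p = 0.229 and 0.297). The histone methylation list did not pass with library totals alone (adjusted p = 0.0984), nor did the inflammatory list after thinning (adjusted p = 0.0673) or the cholesterol list with protein-coding genes only (adjusted p = 0.0607). Counts of list members are for both hairpins at once, and the count adjusted over the list alone was equal to the count over all genes unless given. Thinned to equal protein-coding counts 3679 genes were higher and 3778 lower in this contrast, with library totals alone 2981 were higher, and with no filter 9008 were lower.

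Osteoblast genes fell: of 15 tested, 12 were lower with both hairpins and 1 higher (2 higher adjusted over the list alone), with a median log2 fold change of -2.08 (camera, adjusted p = 4.6e-10, 0.00291 with an estimated correlation). The median was also -2.08 with genes at 0 counts set to their bounds. RUNX2, the master regulator of osteoblast fate (chromosome 6, 45328330 to 45551082), fell from 13.96 ± 0.726 to 8.75 ± 0.294 and 9.78 ± 1.53 CPM (SD, n = 3), log2 fold changes of -0.67 and -0.52. With library totals alone the mean change of RUNX2 was -0.64 and missed the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0522, from 1.95e-27 over the alternatives). IBSP, bone sialoprotein (chromosome 4, 87799554 to 87812435), fell from 4.68 ± 0.548 to 1.42 ± 0.175 and 0.856 ± 0.325 CPM. ALPL, the tissue-nonspecific alkaline phosphatase of mineralising cells (chromosome 1, 21508984 to 21578412), had 989 counts in shControl, 2 in shCTR9#3 and 0 in shCTR9#5, a ratio of 79.2 (95% counting interval 21.9 to 654.7) and a level at least 35.6-fold lower. PTH1R, the parathyroid hormone receptor, had 352, 0 and 2 counts, at least 18.8-fold lower with shCTR9#3, and TNFRSF11B, osteoprotegerin, fell by log2 fold changes of -5.11 and -5.81. COL1A1 fell by log2 fold changes of -4.22 and -4.54. Of the osteoblast genes 9 were lower with both hairpins with library totals alone. Other genes of the mature osteoblast did not pass the filter on low counts and were not tested: BMP2 had 81, 23 and 18 counts per group, SP7 (osterix) 55, 6 and 0, BGLAP (osteocalcin) 30, 3 and 2, and SPP1 (osteopontin) 14, 6 and 8. Control libraries were deeper, so these counts alone do not show a fall. Per library, BMP2 was at 0.29 to 0.45 CPM in shControl, 0.26 to 1.04 in shCTR9#3 and 0.49 to 1.05 in shCTR9#5. In the same order SPP1 was at 0.03 to 0.08, 0 to 0.38 and 0.13 to 0.49 CPM. SP7 was at 0.21 to 0.30, 0.09 to 0.28 and 0 CPM, and BGLAP at 0.11 to 0.17, 0 to 0.19 and 0 to 0.13.

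Matrix and stromal identity lists were lower. Of 32 fibrillar collagens and bone matrix genes 27 fell and 1 rose (median -1.99, camera, adjusted p = 1.54e-33, 0.00179 with an estimated correlation). COL11A1, a minor fibrillar collagen, fell from 3662 ± 20.2 to 116 ± 5.38 and 88.5 ± 6.48 CPM, COL12A1 from 4881 ± 72.2 to 362 ± 10.6 and 292 ± 2.06 CPM, and COL5A3 by log2 fold changes of -4.00 and -4.15 (SD, n = 3). Of 13 mesenchymal stem cell surface markers 12 fell (median -1.98, camera, adjusted p = 1.18e-19, 0.0018 with an estimated correlation), and 1 was higher adjusted over the list alone. THY1 (CD90) fell from 77.6 ± 2.29 to 2.67 ± 0.229 and 1.37 ± 0.389 CPM, CD248 (endosialin) by -4.02 and -4.72, and VCAM1, an adhesion molecule that stromal cells use to hold blood cells, by -3.02 and -3.67. Of 15 smooth muscle and pericyte markers 13 fell and 1 rose (median -3.52, camera, adjusted p = 2.07e-32, 0.00176 with an estimated correlation). CNN1, calponin, fell by -6.84 and -5.42 and LMOD1, an actin nucleator, by -4.45 and -4.54, and exons of TAGLN and ACTA2 overlap those of PCSK7 and FAS on the other strand. Cartilage genes fell too, 7 of 13 lower and 4 higher (5 adjusted over the list alone; median -1.94, camera, adjusted p = 0.000804, 0.0321 with an estimated correlation, 6.15e-06 to 0.297 over the alternatives), with ACAN, aggrecan, at 282 ± 7.86 CPM in shControl against 9.90 ± 0.583 and 7.31 ± 1.51. CILP2 fell by -5.76 and -4.53, and CILP had 229, 2 and 1 counts. Matrix proteases and inhibitors went both ways, 7 of 18 higher, among them ADAMTS5 and MMP3, and 11 lower, among them PLAU and MMP13 (median -0.92, camera, adjusted p = 0.933, 0.0452 to 0.983 over the alternatives), and passed downward with no filter.

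Of 22 TGF-beta pathway genes 13 fell and 8 rose (median -0.51, camera, adjusted p = 0.0013, 0.0436 with an estimated correlation, 1.65e-13 to 0.379 over the alternatives), and for shCTR9#3 alone the adjusted p was 0.1 with an estimated correlation. CCN2, a matricellular target of TGF-beta, fell from 846 ± 8.85 to 64.6 ± 0.546 and 43.9 ± 3.67 CPM, THBS1, thrombospondin, from 9677 ± 83.5 to 745 ± 16.1 and 509.6 ± 8.99 CPM, and the ligand TGFB3 by log2 fold changes of -1.39 and -2.07 (SD, n = 3). THBS1 was not called by limma-voom, with a log2 fold change of -3.97 (-3.97 with edgeR; adjusted p = 0.563, over the alternatives from values too small to store to 0.563). Of 27 Wnt pathway genes 17 fell and 5 rose (median -0.90, camera, adjusted p = 0.00234, 0.0462 with an estimated correlation). For shCTR9#3 and shCTR9#5 alone the Wnt list had adjusted p = 0.0603 and 0.0734 with an estimated correlation. The members that fell most were secreted Wnt antagonists: SFRP1 by -5.12 and -5.02, FRZB by -4.42 and -4.44, SFRP4 by -3.03 and -3.45, and DKK2 with 215, 2 and 2 counts. BMP pathway genes did not pass as a list, with 14 of 29 lower and 8 higher (median -0.13, camera, adjusted p = 0.169, 0.000404 to 0.988 over the alternatives), except downward with no filter. The ligands BMP6 and GDF6 fell by -3.82 and -3.22 with shCTR9#3 and by -3.45 and -3.39 with shCTR9#5. The BMP antagonist CHRDL1 fell by -3.55 and -3.21 and BMPER by -2.82 and -3.17, and exons of BMP6 overlap those of TXNDC5. Among 21 Hedgehog, Notch and FGF genes 11 were lower and 7 higher (median -0.31, camera, adjusted p = 0.238, 0.00685 to 0.555 over the alternatives), and the list passed downward with no filter. FGF7, keratinocyte growth factor, fell from 338 ± 2.81 to 28.7 ± 2.14 and 28.6 ± 1.54 CPM, FGF1 by -3.66 and -3.58 and HHIP by -1.52 and -2.53, while the Notch target HES1 rose by 3.12 and 3.46. Scaled by library totals alone, 2 TGF-beta genes were higher and 7 lower, 4 and 11 BMP genes and 4 and 9 Hedgehog, Notch and FGF genes, and with no filter 5 and 14, 5 and 17, and 4 and 12. After thinning 3 of 23 Wnt genes were higher and 12 lower, and 7 of 28 BMP genes were higher and 9 lower.

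Genes of cell division fell and genes of p53 signalling and stress rose. Of 30 cell division genes 23 fell and 2 rose (median -1.47, camera, adjusted p = 0.000235, 0.0448 with an estimated correlation, 6.49e-14 to 0.163 over the alternatives). RRM2, a subunit of ribonucleotide reductase, fell by log2 fold changes of -5.53 and -4.98, and KIF20A, a mitotic kinesin, had 841, 8 and 1 counts. Of 22 p53 targets and senescence genes 18 rose and 3 fell (median 1.24, camera, adjusted p = 2.46e-09, 0.00291 with an estimated correlation). BBC3 (PUMA), which promotes apoptosis, rose by 3.02 and 3.13 and SESN2, a stress-induced inhibitor of mTORC1, by 2.20 and 2.66, while LMNB1, lamin B1, fell by -3.13 and -2.13. Endoplasmic reticulum and amino acid stress genes rose, 14 of 24 higher and 5 lower (6 lower adjusted over the list alone; median 0.72, camera, adjusted p = 2.06e-06, 0.00693 with an estimated correlation). ATF3, a stress-induced transcription factor, rose by 3.50 and 4.42, PHGDH, the first enzyme of serine synthesis, by 3.07 and 3.26, and SLC7A5, an amino acid transporter, by 2.30 and 2.78. Of 22 inflammatory cytokines and NF-kB targets 16 rose and 5 fell (median 1.72, camera, adjusted p = 0.000879, 0.0301 with an estimated correlation, 1.12e-05 to 0.119 over the alternatives). CXCL12 rose from 0.214 ± 0.0649 to 4.73 ± 0.853 and 2.83 ± 0.499 CPM (SD, n = 3), CXCL5 by 3.94 and 3.60, CCL20 by 4.30 and 4.77 and IL6 by 3.51 and 3.35. Of 21 immediate early genes 12 were higher and 4 lower (median 0.67, camera, adjusted p = 0.0089), with adjusted p = 0.12 with an estimated correlation and from 0.00485 to 0.12 over the alternatives. FOSB rose by 2.44 and 3.28 and KLF2, a flow-responsive factor, fell by -2.87 and -2.78. For shCTR9#3 alone the immediate early list did not pass (camera, adjusted p = 0.0532). Cell division genes were higher in 1 and lower in 19 cases with library totals alone, and 11 endoplasmic reticulum and amino acid stress genes were higher and 2 lower, and after thinning 9 of 17 inflammatory genes were higher and 5 lower.

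Of 22 enzymes and cofactors of H3K27, H3K4 and H3K79 methylation 15 rose and 3 fell (median 0.60, camera, adjusted p = 0.00319, 0.0477 with an estimated correlation, 0.00156 to 0.0984 over the alternatives). Scaled by library totals alone 4 rose and 1 fell, and for shCTR9#3 alone the list had adjusted p = 0.0607 with an estimated correlation. JARID2, a cofactor of Polycomb repressive complex 2, rose by log2 fold changes of 1.62 and 1.83, the H3K27 demethylase KDM6B by 1.56 and 1.86 and the H3K4 methyltransferase SETD1A by 0.90 and 1.20, while ASH2L, a core subunit of H3K4 methyltransferase complexes, fell by -1.23 and -1.69. Of 25 elongation and H2B ubiquitylation factors 9 were higher and 4 lower with both hairpins (10 and 4 adjusted over the list alone; median 0.16, camera, adjusted p = 0.287). TCEA1 (TFIIS) rose by 0.99 and 1.13, SUPT5H by 0.51 and 0.76 and the FACT subunit SSRP1 by 0.57 and 0.60, while NELFE, a subunit of the pausing factor NELF, fell by -1.14 and -1.13. SUPT5H and SSRP1 lost their calls with library totals alone (adjusted p = 0.091 and 0.125, from 2.63e-36 and 1.88e-15 over the alternatives). On leaving out 1 library 5 to 7 members of this list were higher and 3 to 5 lower, with no filter 4 and 6, and with library totals alone 1 and 1. Of 21 replication-dependent histone genes 5 were higher and 3 lower (4 and 3 adjusted over the list alone; median 0.22, camera, adjusted p = 0.427), with H1-4 higher by 1.31 and 1.33, H1-3 by 4.40 and 3.82, and H1-5 lower by -2.82 and -2.72. H3C2 had 361, 3 and 5 counts, and on leaving out 1 library 3 to 5 of these genes were higher, with library totals alone 2 were higher and 2 lower, and with no filter 2 and 5. HOX genes, of which 8 of 22 were higher and 1 lower (6 and 1 adjusted over the list alone; median 0.29, camera, adjusted p = 0.381), included HOXA9 at 0.97 and 1.19, HOXB7 at 0.77 and 0.92, HOXA6 at 0.92 and 1.02 and HOXA4 at 0.90 and 1.05. On leaving out 1 library 2 to 6 HOX genes were higher, with no filter 2 were higher and 4 lower, and with library totals alone 1 was higher. HOXA4 lost its call with no filter and without shCTR9#5 replicate 3 (adjusted p = 0.0669 and 0.0584, from 0.00233 to 0.0669 over the alternatives), and HOXA6 after thinning (adjusted p = 0.0528, from 0.000474 over the alternatives). HOXA9 shares 1494 exon bases with a readthrough transcript.

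Metabolic and housekeeping lists were mixed. Cholesterol synthesis genes were lower in 14 of 21 and higher in 2 (median -0.75, camera, adjusted p = 0.00426), with adjusted p = 0.0909 with an estimated correlation and from 4.63e-09 to 0.0909 over the alternatives. The sterol enzymes SQLE and MSMO1 fell by log2 fold changes of -2.06 and -2.13 with shCTR9#3 and of -2.13 and -1.68 with shCTR9#5. All 13 mitochondrial mRNAs were lower with both hairpins (median -0.60, camera, adjusted p = 0.00172), with adjusted p = 0.305 with an estimated correlation and from 1.44e-12 to 0.305 over the alternatives. COX1 fell from 3173 ± 245 to 1779 ± 44.0 and 1508 ± 60.2 CPM, ATP6 by -1.17 and -1.44, COX2 by -0.90 and -1.06 and COX3 by -1.55 and -1.71, whereas mitochondrial genes held 3.57% ± 0.236, 3.98% ± 0.0348 and 3.55% ± 0.232 of protein-coding counts in the 3 groups (SD, n = 3). Nuclear genes of oxidative phosphorylation had 3 of 31 higher and 5 lower (median 0.02, mean -0.01, camera upward, adjusted p = 0.901), with SDHA at 0.64 and 0.73, UQCRC1 at -0.66 and -0.78, ATP5F1A at -0.53 and -0.64 and NDUFS1 at -0.46 and -0.59. Ribosomal protein genes had 6 of 34 higher and 7 lower (median 0.01, mean -0.000655, camera upward, adjusted p = 0.796), with RPLP1 at 0.51 and 0.87, RPS19 at 0.38 and 0.72, RPL10A at -0.55 and -0.74 and RPL35 at -0.66 and -0.48. Of 24 hypoxia and glycolysis genes 8 were higher and 11 lower (median -0.04, mean 0.09, camera upward, adjusted p = 0.991): VEGFA rose by 2.48 and 2.55, KDM3A by 1.53 and 1.68 and PDK1 by 1.39 and 1.23, and the glycolytic enzyme ENO1 fell by -1.78 and -1.83. Without a filter on low counts the oxidative phosphorylation, ribosomal protein and hypoxia lists passed downward (camera, adjusted p = 0.00388, 0.000115 and 0.022, up to 0.987, 0.987 and 0.998 over the alternatives). Their medians then stood at -0.28, -0.28 and -0.33, a downward shift that other lists shared. With library totals alone SDHA, NDUFS1, RPLP1, RPS19 and RPL35 lost their calls (adjusted p = 0.0587, 0.0783, 0.0567, 0.169 and 0.0608, the highest of their alternatives, the lowest being 2.38e-26, 3.14e-36, 4.74e-27, 2.09e-18 and 2.79e-39). On leaving out 1 library 4 to 6 ribosomal protein genes were higher and 7 to 11 lower. With no filter 2 ribosomal protein genes were higher and 18 lower, and 1 and 12 oxidative phosphorylation genes. In the oxidative phosphorylation and ribosomal protein lists library totals alone, with edgeR, called 0 genes with both hairpins, and 0 at an unadjusted p under 0.05. With the same scaling 4 of the 13 mitochondrial mRNAs were lower, 1 cholesterol gene was higher and 10 lower, and 4 hypoxia genes were higher and 4 lower.

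Adipocyte genes, the other main fate of these cells, split as well, 7 of 20 higher and 8 lower (median -0.14, also with genes at 0 counts at their bounds, mean -0.54, camera upward, adjusted p = 0.158, 0.0474 to 0.922 over the alternatives), and passed upward with DESeq2. LPL, lipoprotein lipase, had 610 counts in shControl and 0 with either hairpin, at least 32.6-fold and 21.98-fold lower, while its inhibitor ANGPTL4 rose from 4.71 ± 0.226 to 50.5 ± 1.65 and 47.7 ± 2.84 CPM (SD, n = 3) and DGAT2 of triglyceride synthesis rose by log2 fold changes of 3.23 and 3.41. Glucocorticoid-induced genes were higher in 9 of 18 and lower in 5 (median 0.40, camera, adjusted p = 0.281), with the metallothioneins MT2A at 1.76 and 1.66 and MT1X at 1.72 and 1.94, the thiamine transporter SLC19A3 at 3.02 and 3.22 and CRISPLD2 at -1.89 and -1.96. Heat shock genes had 9 of 15 higher and 4 lower (median 0.41, camera, adjusted p = 0.901), with HSPA4L at 2.12 and 2.16 and HSPE1 at 0.88 and 0.85 but the small heat shock proteins CRYAB at -2.26 and -2.29 and HSPB1 at -1.52 and -1.68. Interferon response genes had 4 of 18 higher and 6 lower (median 0.09, mean -0.26, camera upward, adjusted p = 0.933), with IFI6 at 1.54 and 2.17, BST2 at -1.73 and -2.56, XAF1 at -1.11 and -2.34 and MX2 at 323, 6 and 1 counts. On leaving out 1 library 1 to 4 interferon response genes were higher. With library totals alone 1 interferon response gene was higher and 2 lower, 1 and 2 heat shock genes, and 6 and 3 glucocorticoid-induced genes, and with no filter 1 and 6 interferon response genes and 4 and 5 heat shock genes. After thinning 3 of 9 interferon response genes were higher and 1 lower. Markers of other cell types were few. The endothelial genes TEK and EGFL7 were the 2 tested of 14 and neither was called, at 1.56 ± 0.115 and 1.32 ± 0.0826 CPM in shControl. Of 17 blood cell markers 2 could be tested, with CD14 lower by -2.44 and -1.40 and CD68, a lysosomal glycoprotein, higher by 0.84 and 0.58. CD68 lost its call with library totals alone (adjusted p = 0.053, from 2.79e-20 over the alternatives). Of 12 epithelial markers 4 could be tested, with KRT18 and KRT8, whose exons overlap by 135 bases, higher by 1.37 and 0.92 with shCTR9#3 and by 1.54 and 1.56 with shCTR9#5, and KRT14 at 634, 4 and 2 counts.

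**Figure D3:**
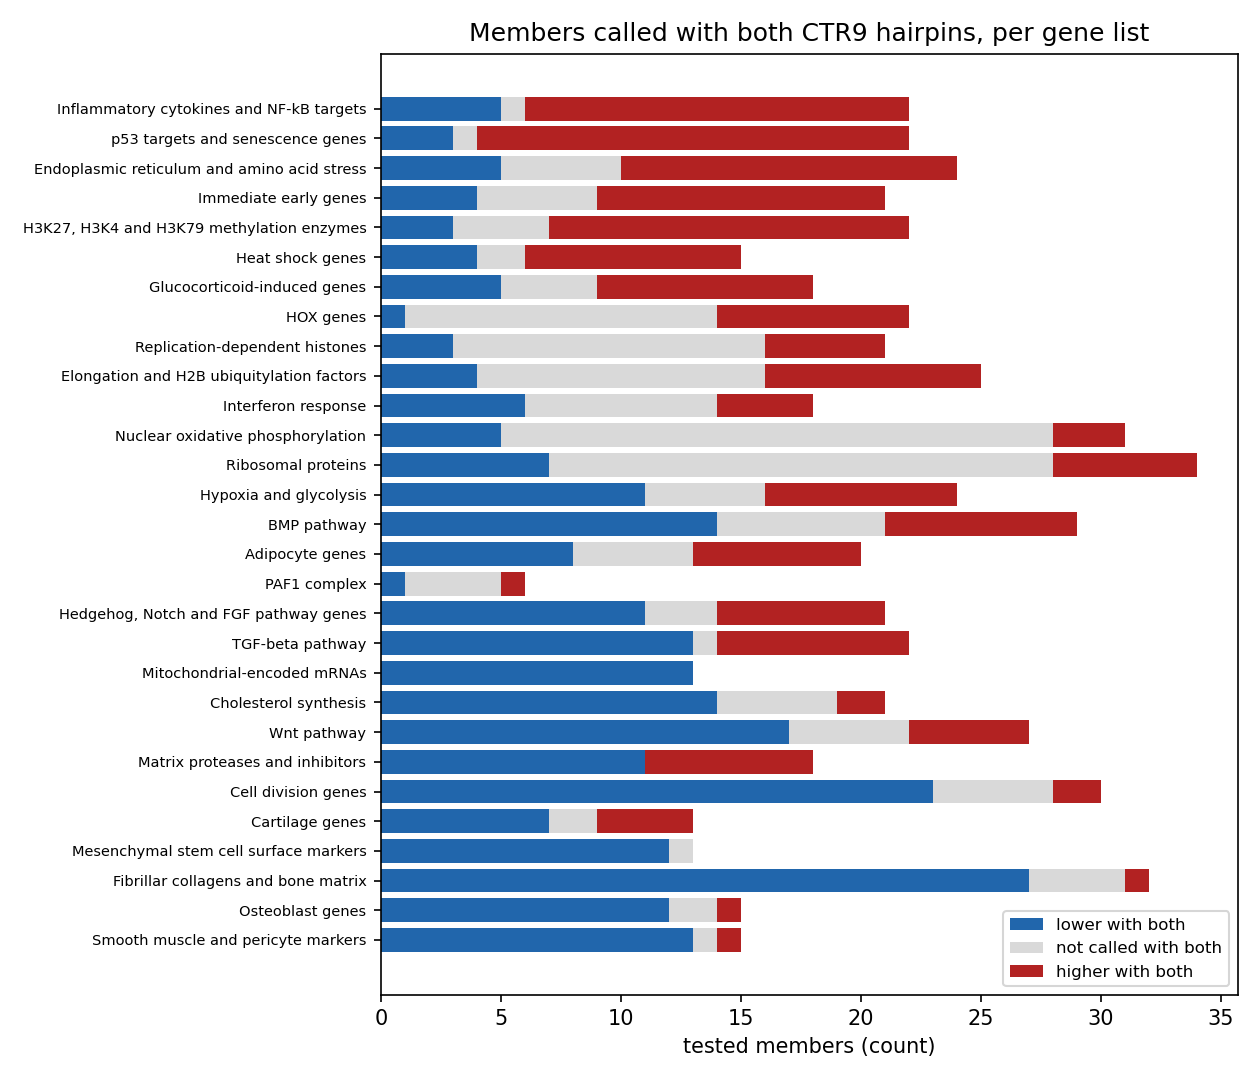
Members of each gene list that were lower with both hairpins, not called with both in 1 direction, or higher with both, as stacked bars counted in tested genes on an axis from 0. Lower members make up 12 of 15 osteoblast genes, 27 of 32 matrix genes and 13 of 15 smooth muscle and pericyte markers, and higher members make up 18 of 22 p53 targets and senescence genes.

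Between the hairpins themselves, few genes differed. TNC, tenascin-C of the matrix (chromosome 9, 115019575 to 115118244), stood at 109 ± 1.14 CPM in shCTR9#3 and 51.9 ± 2.13 in shCTR9#5 against 622 ± 5.67 in shControl (SD, n = 3), a log2 difference between the hairpins of -1.07 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.22e-08). TMEM119, a membrane protein that promotes osteoblast differentiation, was lower by -0.97 in shCTR9#5 (adjusted p = 0.00586). GREM1, a BMP antagonist (chromosome 15, 32718004 to 32745106), was higher in shCTR9#5, at 41.3 ± 1.90 against 25.6 ± 0.243 CPM (156 ± 1.89 in shControl; log2 difference 0.69, adjusted p = 3.87e-05). The mitochondrial tryptophan transfer RNA TRNW differed by 0.79 (adjusted p = 0.00369). The edgeR quasi-likelihood test called 94 genes higher and 233 lower in shCTR9#5 than in shCTR9#3 at a Benjamini-Hochberg adjusted p under 0.05. CTR9 itself did not differ (log2 difference 0.09, adjusted p = 0.898). The counts ranged from 1 to 218 higher and from 10 to 350 lower over the alternatives, and leaving out shCTR9#3 replicate 1 gave 40 and 135. CADM3, APOL1, THY1, TNXB and C6orf136, also called here, lost their calls in 7 to 15 of the alternatives. TMEM119, TRNW and GREM1 lost theirs with library totals alone (adjusted p = 0.226, 0.615 and 0.629, from 3.34e-05, 6.75e-08 and 3.07e-17 over the alternatives), and TMEM119 and TRNW also with limma-voom (adjusted p = 0.15 and 0.0685).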

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

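The tests of depth, library batch, short RNA, the library with the highest ribosomal RNA share and changes that go further with shCTR9#5 were chosen only after the result was seen. Genes that differed between the CTR9 hairpins were singled out because the difference itself passed the edgeR quasi-likelihood test. There were 94 higher and 233 lower genes in shCTR9#5 than in shCTR9#3. Log2 differences were 0.88 for TNXB, 0.83 for C6orf136, 0.79 for TRNW and 0.69 for GREM1, and -1.46 for CADM3, -1.10 for APOL1, -1.07 for TNC, -0.97 for TMEM119 and -0.96 for THY1. Exons of TNXB overlap those of CYP21A2 by 1788 bases and exons of C6orf136 overlap those of DHX16 by 567 bases, so both are uncertain. The 6 libraries of both CTR9 hairpins allow 10 splits, too few for a share under 0.05. The real split gave 60 higher and 122 lower genes, and the others gave at most 27 in either direction.

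A difference between the hairpins could come from shCTR9#5 replicate 2, which had the highest ribosomal RNA share. Without it 202 genes were called, 181 of the 327 genes kept call and direction, and the median ratio of their log2 differences without it to those with it was 1.005 (quartiles 0.940 and 1.07), which argues against that library as the whole source. In 84.7% of the 327 called genes the difference had the direction of the mean change against shControl, as changes of the same kind that go further with shCTR9#5 would give. The slope of the log2 fold changes across all genes was 1.01, so a stronger effect of shCTR9#5 on all genes is not shown. Effects of either hairpin on other transcripts were not tested and stay open.

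Large matched changes with both hairpins may have a technical part, because all knockdown libraries were shallower than all control libraries. Thinned to equal protein-coding counts, with total counts still unequal, genes called with both hairpins had a median ratio of thinned to full log2 fold change of 0.986 (quartiles 0.882 and 1.11, 7949 genes). For the 6399 protein-coding genes it was 0.983 (quartiles 0.883 and 1.11). Thinning draws counts at random and keeps each gene's expected share of its library, so a nearly unchanged fold change was largely fixed in advance. These ratios show only that the estimates did not depend on how many counts were drawn. They cannot decide whether the shallower libraries were distorted in other ways. They cover only those of the 9007 genes called with both hairpins that were still tested after thinning. The 10 most abundant protein-coding genes of a library held on average 24.9%, 10.5% and 10.0% of protein-coding counts in shControl, shCTR9#3 and shCTR9#5. Without the 50 protein-coding genes most abundant in shControl 99.7% of the other genes called with both hairpins kept their call. TMM scaling already trims genes of extreme change or abundance, so this outcome was largely fixed in advance. It shows only that the other calls did not depend on these 50 genes. Ribosomal RNA, which took most of the counts in every library, was left in. In the fit without structured RNA classes, ribosomal RNA among them, 93.1% of all genes called with both hairpins kept call and direction. Genes removed there counted as lost. No label names a library batch, and only the gap in depth raises one. Because 0 control libraries had a protein-coding total in the range of the knockdown libraries, no value here decides for or against it, and it stays open beside loss of CTR9 as a candidate explanation.

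Splits of the libraries were set against these counts. The splits of 6 libraries number 10, too few for a share under 0.05, and 1 of 10 reached the real count in each comparison, with 5954 higher and 6272 lower genes for shCTR9#3 and 5363 higher and 5876 lower for shCTR9#5, and at most 0 in the others. Among 100 splits of the 9 libraries, 3 gave as many genes higher with both hairpins (4382, highest other 4394) and 1 as many lower (4625, highest other 4616), both a share under 0.05. Splits that mix controls with knockdown libraries raise the spread within groups and so call few genes. The shares therefore cannot exclude a batch, or chance if the libraries of a group are not independent. For the mean of the hairpins 1 split reached 5788 higher (highest other 5720) and 1 reached 5761 lower (highest other 5698), and 4 reached the 15 gene lists (highest other 15). The near-equal counts came from the 3 other splits drawn that kept all controls as the control group, so they show the difference of the controls from the other libraries. In 95 other splits 0 genes were called, yet 41 of these put at least 9 gene lists past the threshold and the highest was 13, so the number of lists says less than the gene counts. The remaining split did not keep all controls as the control group. It called 2900 higher and 2967 lower genes in the mean contrast, 0 with both hairpins, and put 14 lists past the threshold.

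Nuclear transfer RNA genes were higher with both hairpins in 60 of 62. Their quartiles in shControl were 0.0382 and 0.191 CPM, so most passed the filter on low counts only through the knockdown libraries. The share called higher was therefore largely fixed in advance. Reads shared among copies could make a few transcripts count many times. The higher genes belonged to 25 of 26 anticodon families. With 60 of 62 genes higher nearly every family had to be among them, so this count cannot decide about shared reads. Reads shared within a family or between similar families were not tested. Within each CTR9 hairpin the transfer RNA genes named above ran in the order of the ribosomal RNA share of the libraries, so a technical part stays open. More short RNA kept in the knockdown libraries may contribute and stays open: 5 small nucleolar RNA genes matched on length and control CPM had a median mean log2 fold change of 2.67 (quartiles 2.62 and 3.22), below the lower quartile of 3.57 of the transfer RNAs but in the same direction. No biological explanation was tested.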

How the results depend on the processing

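The fits on protein-coding genes only, on thinned libraries and without structured RNA classes were chosen after seeing the data. CTR9 stayed lower and called in all 22 alternatives run for it, with log2 fold changes from -3.41 to -3.02 for shCTR9#3 and from -3.34 to -2.97 for shCTR9#5. Of genes called with both hairpins, 99.2% were shared with relative log expression, 95.5% with DESeq2, 94.2% with limma-voom, 64.7% after thinning and 47.4% with library totals alone, and 0 turned direction. Named genes kept direction and side of the threshold in 3223 values, with 121 weaker, 3 stronger and 7 reversed, and lists in 590, with 12, 5 and 28. The cause was not tested except where given.

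With library totals alone 3215 genes were higher and 2533 lower in shCTR9#3, 1903 higher in shCTR9#5, 1835 and 2469 with both, 2981 higher in the mean, and 1 and 10 between the hairpins; TEK was at -0.0207, Adipocyte genes at -0.23 and Interferon response at -0.00560. Thinning, which leaves fewer counts, gave 3276 and 3409 genes for shCTR9#3, 2834 higher with both, 3679 and 3778 in the mean, 54 and 138 between the hairpins, and CDC73 at 0.00767. No filter, which adds low genes, gave 8089 lower genes for shCTR9#3, 7792 for shCTR9#5, 6945 for both, 9008 for the mean and 218 higher between the hairpins. It put RTF1 at -0.0433, C6orf136 at -0.13, TEK at -0.19, Elongation factors at -0.13, Adipocyte genes at -0.43, Interferon response at -0.20, Heat shock at 0.12, Hypoxia at -0.33, Nuclear oxidative phosphorylation and Ribosomal proteins at -0.28, and histones at -0.0797. In the main fit RTF1 was at 0.25, Elongation factors at 0.16, Heat shock at 0.41, Hypoxia at -0.04 and Ribosomal proteins at 0.01. All of these moved downward by similar amounts, as a shift of the scaling common to all genes would give. The added lower calls, the reversals and the lists that passed downward with no filter were not told apart from that shift. A log2 fold of at least 1, stricter by construction, left 2161 and 2307 genes for shCTR9#3, 2270 and 2527 for shCTR9#5, 1831 and 2056 for both, 2182 and 2383 for the mean, and 5 and 13 between the hairpins.

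Between the hairpins DESeq2 called 145 and 350, limma-voom 28 and 64, 6 libraries per fit 60 and 122, a threshold of 0.01 31 and 84, and protein-coding genes only 142 higher. A reversed list is one whose camera direction changed, and its value is its median change. With medians of unchanged sign these were Matrix proteases with DESeq2 (-0.93) and protein-coding genes only (-0.91), Hypoxia with DESeq2 (-0.0470), limma-voom (-0.0344), the block (-0.0351) and a mean CPM of at least 5 (-0.35), Nuclear oxidative phosphorylation (0.0276) and Ribosomal proteins (0.0190) with limma-voom, and Interferon response with the strict filter (0.0739). Leaving out each library gave 40 to 100 higher and 106 to 193 lower genes between the hairpins, TEK from -0.0752 to 0.19, the gene list Hypoxia and glycolysis from -0.0878 to -0.0465, the gene list Ribosomal proteins from -0.0834 to 0.0176 and Matrix proteases from -0.99 to -0.90.

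The replicate numbers were checked as a block: 0 of 9 same-number pairs had a correlation over 0.1 (-0.0562 to 0.0975), and the block gave 5163 and 5196 genes for shCTR9#3, 4990 and 5035 for shCTR9#5, and 73 and 169 between the hairpins. Not run were the log2 fold minimum for lists, and the fit of 6 libraries for the mean, for lists and for the mean change of named genes. Depth limits which low genes were tested: BMP2, SP7, BGLAP and SPP1 did not pass the filter.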

Other observations

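The tests of gene length, of GC content and of the SRF, YAP and TEAD, and NRF2 lists were chosen only after the result was seen. Small RNA classes were counted by calls with both hairpins. Of 62 nuclear transfer RNAs 60 were higher with both (median log2 fold change 4.76 with shCTR9#3 and 5.24 with shCTR9#5), and of 180 small nucleolar RNAs 152 were higher and 5 lower (1.37 and 1.801). Most of the transfer RNAs passed the filter on low counts only through the knockdown libraries, with quartiles of 0.0382 and 0.191 CPM in shControl. Their share called higher and their medians were thus largely fixed in advance. All 4 Y RNAs, 12 of 24 small nuclear RNAs and 2 of 3 vault RNAs were higher. Mitochondrial transfer RNAs were higher in 11 and lower in 3 of 22, and microRNAs were higher in 15 and lower in 10 of 45 (median 0.174 with shCTR9#3 and -0.0939 with shCTR9#5). The RNase MRP RNA (-0.22 and -0.05) and 3 small cytoplasmic RNAs were not called with both. Long noncoding RNAs were higher in 348 and lower in 208 of 1027, and protein-coding genes were higher in 3016 and lower in 3924 of 12100.

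Gene lists added after the data were seen gave hypotheses only, and the lysosome list was written down before its own test was run. All 18 cytoskeletal targets of the transcription factor SRF were lower with both hairpins (median -2.36, camera, adjusted p with an estimated correlation 0.000483), consistent with lower SRF activity, and 2 of them are in the lists above. Of 22 YAP and TEAD targets 16 were lower and 1 higher (-1.28, 0.00107), which suggests lower YAP and TEAD activity, and 4 are in the lists above. Of 20 NRF2 targets 13 were higher and 5 lower (1.17, 0.00498), consistent with higher NRF2 activity. Higher lysosome gene expression was not shown, with 13 of 24 genes higher and 6 lower (median 0.29, camera, adjusted p = 0.0586, 0.0852 with an estimated correlation). It was not excluded either, although the bound written beforehand took a missed threshold as evidence against it, because a p that misses the threshold does not show the lack of a shift. A library batch is open for all of these.

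Loss of elongation in long genes could have lowered them most. Across 12100 protein-coding genes, which are not independent replicates, the mean log2 fold change had a Spearman rho of -0.067 with the length from first to last exon, and 2397 genes of at least 100 kb had a median of -0.18 against -0.03 for the others, which argues against length as a main factor. GC content and log length, taken from the longest GENCODE transcript of each gene and not from the RefSeq exons counted, explained 0.357% of the variance in 11759 genes.

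In opposite directions with each hairpin were C3 (log2 fold changes 0.29 with shCTR9#3 and -0.44 with shCTR9#5), MIS12 (0.54 and -0.61), ITFG1 (0.17 and -0.29), PPIB (0.18 and -0.17), CUL9 (0.22 and -0.28), COL6A3 (0.22 and -0.17), COL4A4 (0.41 and -0.47) and FAP (0.18 and -0.22). The difference between the hairpins passed for all but CUL9 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0561). These genes were chosen for opposite calls in the same libraries, so this was largely fixed in advance and adds no support.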
